A study of Caenorhabditis elegans with 8 samples.

How the data were processed

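Poly(A) RNA of whole day 1 adult Caenorhabditis elegans was sequenced by the authors from 4 wild-type (N2) and 4 atf-6 cultures, with a stranded TruSeq library kit and 75 cycles on an Illumina NextSeq500, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name Salmon 0.9.1, STAR 2.5.3a, DESeq2 1.19.51 and the genome build WBcel235, with no role or order. Whether strand was used in the quantification is not given in the sources used here.

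The values used were of 4 kinds. The authors deposited a table of estimated counts for 46093 genes, in whole numbers and not normalized for library size. Its values were compared with the per-sample transcript files: they lay closer to transcript abundances rescaled by mean effective length and library total (median absolute log2 difference 0.00948 to 0.0101 per library) than to plain sums of reads in 7 of the 8 libraries. A second deposited table of normalized signal equals these counts divided by 1 size factor per library and was used only for this check. Per the file headers, the per-sample files hold for 58105 transcripts the estimated counts (reads), the TPM (abundance scaled for length and depth) and the effective length that the quantifier assigned. Table columns carry library numbers rather than titles, and were tied to samples through the number in each sample's own deposited file. An offset for transcript length, fitted to this table, covers only a length trend left in it. Estimates for near-identical genes or overlapping isoforms depend on how the quantifier divided shared reads.

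Depth was 12664222 to 21698298 estimated counts per library. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 3.72). Gene symbols came from a gene name table (43540 of the identifiers) and otherwise from the Ensembl release 115 annotation of WBcel235, which also gave positions. GC content was not tested, since no genome sequence was used here.

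Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (12375 genes kept), TMM normalization, a robust quasi-likelihood fit with the strain as the factor, a two-sided F-test and Benjamini-Hochberg adjustment, with 0.05 as the threshold. CPM values are relative to TMM-adjusted library sizes, and errors of means are SDs over 4 libraries. Log2 fold changes are atf-6 minus wild type. Their SE was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.116. TMM, RLE and upper-quartile scaling put the median log2 fold change of all genes at 0.00191, -0.00923 and 0.0279.

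Before the data were examined, 42 gene lists (pathways, tissues, germline and stage markers, and families by symbol prefix) were fixed and tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Each list was also counted with p-values adjusted over all genes and adjusted over the list alone. Of 645 entries in these lists, 10 had no row in the table. Lists can share genes: crt-1, for example, is in the ER chaperone and the calcium lists. The rule for named genes was also fixed then. It takes atf-6, hsp-3, hsp-4, crt-1, itr-1, mcu-1, xbp-1, ire-1 and pek-1 always; the 12 largest rises and 12 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap; and up to 4 members of each list past the threshold with the smallest adjusted p. Values per replicate are given for the first set and for the 3 largest changes in each direction. Further members are named where adjustment over a list alone called them, chosen after their values were seen.

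The model was tested on simulated data with the means and library sizes of these 8 libraries (12258 genes, 200 of them changed). It recovered 50%, 72%, 96% and 92% of genes changed 1.5-, 2-, 3- and 4-fold, called 12 unchanged genes, and called 0 genes when none was changed. Each gene was drawn independently, so variation that genes share between libraries was absent. These counts therefore do not bound the false calls in the real libraries. Alternatives fixed in advance were RLE and upper-quartile normalization, no filter on low counts, at least 10 counts in 4 libraries, DESeq2 1.42.0 (on all genes, with its own independent filter), limma-voom, the replicate number as a block, plain sums of the transcript reads, leaving out each library in turn, a threshold of 0.01, and for the lists an estimated correlation, fry and leaving out genes within 2 Mb of atf-6. Added after seeing the data were 1 surrogate variable (sva 3.50.0), an offset for transcript length, and a fit without the 2 libraries at the ends of that variable. The 35 splits of the 8 libraries into 4 and 4 were refitted with the same model. Sums over 6 families and lists were compared with exact permutation tests, with Benjamini-Hochberg adjustment over the 6.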

Results

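Whole-worm gene expression was measured by poly(A) RNA-seq in 2 strains of the nematode Caenorhabditis elegans, the wild-type laboratory strain N2 and a strain labelled atf-6, with 4 libraries per strain. ATF-6 is a transcription factor anchored in the endoplasmic reticulum (ER) membrane that acts in the unfolded protein response (UPR). The worms were day 1 adults grown at 20 °C, collected 72 h after synchronized first-stage larvae were put on food, with about 1000 worms per replicate. The labels describe the 4 replicates as independent. Total estimated counts per library were 12664222, 21381351, 17201645 and 21698298 in wild-type replicates 1 to 4 and 14273326, 17423440, 19396448 and 18019872 in atf-6 replicates 1 to 4. The series title ties atf-6 to lifespan and to calcium exchange of the ER with mitochondria, so the comparison asks which transcripts, ER and calcium genes among them, differ in level between the strains.

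The atf-6 transcript itself was not lower in the libraries labelled atf-6. The gene (WBGene00000222, protein-coding, chromosome X, 12480948 to 12484904 on the plus strand, build WBcel235) had 10.8, 12.803, 13.2 and 12.5 CPM (counts scaled to a common library size) in wild-type replicates 1 to 4 and 16.05, 15.1, 14.7 and 14.1 CPM in atf-6 replicates 1 to 4. The means were 12.31 ± 1.06 and 14.99 ± 0.804 CPM (SD, n = 4 each). The log2 fold change of 0.28 (SE 0.0911) did not pass edgeR's quasi-likelihood test (adjusted p = 0.346), although the 2 groups did not overlap. The labels name no allele, and a level for the whole transcript does not show whether a part of it is deleted or altered, so this value does not check the strain labels. The libraries are called atf-6 here by their label.

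In the fixed lists, no ER chaperone or folding enzyme and no UPR sensor passed edgeR's test over all genes. Outside them, txdc-12.1, named after its values were seen and by its name a relative of the ER thioredoxin-domain protein TXNDC12, rose from 10.2 ± 1.09 to 21.3 ± 1.75 CPM (SD, n = 4; log2 fold change 1.06, SE 0.102, edgeR adjusted p = 0.00125). ckb-2, a choline kinase of phosphatidylcholine synthesis that was part of the ER list, rose from 11.9 ± 2.55 to 29.3 ± 3.82 CPM (SD, n = 4; log2 fold change 1.31, SE 0.150, edgeR adjusted p = 0.00369). crt-1 (WBGene00000802, chromosome V, 6098992 to 6100542), which encodes calreticulin, the calcium-binding chaperone of the ER lumen, had 994 ± 144 CPM in wild type and 657 ± 94.8 CPM in atf-6, a log2 fold change of -0.60 (SE 0.125). Its groups did not overlap, but it missed the threshold over all genes (edgeR adjusted p = 0.0681). It passed when p-values were adjusted over the list alone, both among ER chaperones (adjusted p = 0.00643) and among calcium-handling genes (adjusted p = 0.0193). The BiP homologs hsp-3 and hsp-4, ER chaperones of the Hsp70 class, had log2 fold changes of -0.02 (SE 0.118) and 0.05 (SE 0.0990), and neither passed.

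Of 20 tested genes in the list of ER chaperones and folding enzymes, 1 rose (ckb-2, which is neither), 0 fell and 19 did not pass over all genes tested with edgeR, and 7 had an unadjusted p under 0.05. DESeq2 called 2 higher, ckb-2 and dnj-7 (adjusted p = 0.0369), and 1 lower, crt-1, of 20 tested. With plain read sums edgeR called 2 higher, ckb-2 and dnj-27 (adjusted p = 0.0440). Adjusted over the list alone, 4 rose, namely ckb-2, dnj-7, dnj-27 and C14B9.2, and 1 fell, crt-1. dnj-7, dnj-27 and C14B9.2 had log2 fold changes of 0.27, 0.33 and 0.27 (SE 0.0607, 0.0869 and 0.0731). The list as a set did not pass the camera test (adjusted p = 0.499). Its median of -0.01 and mean of 0.06 had opposite signs, the camera direction being up. The fry test for change in either direction gave an adjusted p of 0.00296 for this list. That test included ckb-2 and was not run without it, so it does not show a change of the chaperones themselves. The list did not pass fry for movement in 1 direction (adjusted p = 0.705). The list named UPR sensors and transcription factors had 5 tested genes, xbp-1, ire-1, pek-1, atf-4 and gcn-2. None of them passed over all genes or adjusted over the list alone. In edgeR 0 had an unadjusted p under 0.05, and 0 passed with DESeq2. Among 30 calcium-handling genes, 0 passed over all genes with edgeR (5 at an unadjusted p under 0.05, and crt-1 alone of 31 tested with DESeq2) and 1 (crt-1) when adjusted over the list alone. itr-1, the inositol trisphosphate receptor of the ER, had a log2 fold change of 0.25 (SE 0.148) and mcu-1, the mitochondrial calcium uniporter, of -0.03 (SE 0.0690), and neither passed. The signs of hsp-3, hsp-4, ire-1, pek-1 and mcu-1 changed with the setting.

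**Figure D1:**
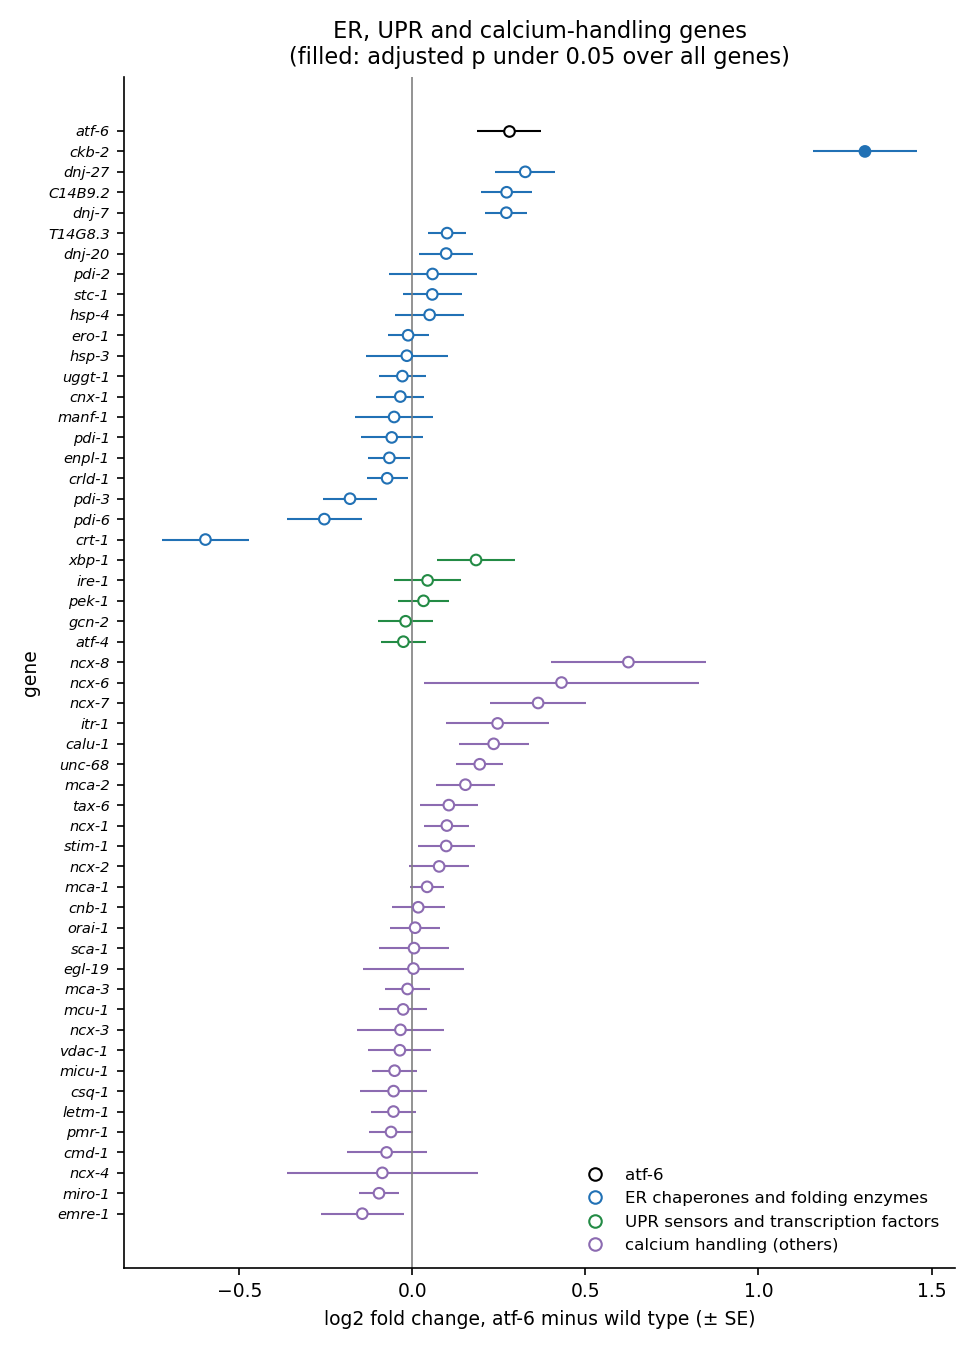
Log2 fold change (atf-6 minus wild type, horizontal axis, bars show the SE), with 1 point per gene. Shown are atf-6, the tested members of the lists of ER chaperones and folding enzymes and of UPR sensors and transcription factors, and the other calcium-handling genes. The filled point, ckb-2 at 1.31, is the gene past an adjusted p of 0.05 over all genes; crt-1 lies at -0.60.

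By replicate, crt-1 was at 873, 958, 1203 and 942 CPM in wild type and 765, 704, 559 and 599 CPM in atf-6. hsp-3 (chromosome X, 6089028 to 6092124) measured 525, 582, 734 and 601 CPM against 695, 639, 534 and 547 CPM. Values of hsp-4 (chromosome II, 7350112 to 7352645) were 462, 459, 533 and 470.2 CPM against 563, 543, 422 and 463 CPM. itr-1 (chromosome IV, 7675174 to 7696930) had 51.9, 47.02, 35.2 and 43.9 CPM in wild type and 42.8, 44.8, 64.2 and 58.5 CPM in atf-6. For mcu-1 (chromosome IV, 5937447 to 5939230) the CPM values were 93.5, 86.6, 78.4 and 85.4 and 81.0, 79.7, 89.1 and 87.5. The UPR transcription factor gene xbp-1 (chromosome III, 4193809 to 4195358) gave 202, 212, 262 and 227 CPM in wild type and 303, 272, 219.8 and 231 CPM in atf-6 (log2 fold change 0.18, SE 0.112, edgeR adjusted p = 0.857). The UPR sensor kinases ire-1 (chromosome II, 8112243 to 8124910) and pek-1 (chromosome X, 11410176 to 11414887) had log2 fold changes of 0.04 (SE 0.0966) and 0.03 (SE 0.0746). Their values were 126, 113, 103.9 and 116 against 101, 113, 139.7 and 118 CPM for ire-1 and 58.5, 58.2, 50.96 and 64.6 against 59.5, 61.4, 58.2 and 58.6 CPM for pek-1. crt-1 passed with DESeq2 (adjusted p = 0.000716) and without a filter on low counts (adjusted p = 0.0158). Its adjusted p ranged from 0.0697 to 0.222 when 1 library was left out and from 0.0611 to 0.160 under RLE or upper-quartile scaling, another count filter, limma-voom or plain read sums. With 1 surrogate variable as a covariate, chosen after seeing the data, crt-1 passed (adjusted p = 1.64e-08), as did xbp-1 (log2 fold change 0.23, adjusted p = 0.000731). The ER list then had 4 genes up (ckb-2, dnj-7, dnj-27 and C14B9.2) and 3 down (crt-1, pdi-3 and pdi-6). That variable was estimated from the same libraries and treated as known, so these p-values can be too small. Without wild-type replicate 3 and atf-6 replicate 3, also chosen after seeing the data, crt-1 had a log2 fold change of -0.42 (edgeR adjusted p = 0.0701). In every other setting the adjusted p of xbp-1 was at least 0.227.

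Over all genes, 101 of 12375 tested passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 88 higher and 13 lower in atf-6. An unadjusted p under 0.05 was found for 866 genes, where chance alone gives a share of about 0.05 of the tested genes. All 101 had groups that did not overlap, which held for 5.79% of the tested genes, where chance gives 2.86%. The top of the higher genes was a cluster of 3 neighbouring genes on chromosome V. Y102A5C.36 (WBGene00044213, protein-coding, 16926922 to 16927445), and the annotated pseudogenes Y102A5C.5 (WBGene00014954, 16928328 to 16928999) and Y102A5C.6 (WBGene00014955, 16929167 to 16930063) rose 7.84-, 6.93- and 6.104-fold. Their log2 fold changes were 2.97 (SE 0.229), 2.79 (SE 0.0983) and 2.61 (SE 0.146), with edgeR adjusted p of 0.000198, 3.13e-07 and 1.29e-05. By replicate, Y102A5C.36 was at 0.531, 0.659, 1.21 and 1.01 CPM in wild type and 8.17, 7.23, 5.50 and 6.46 CPM in atf-6. Y102A5C.5 was at 3.34, 3.15, 3.69 and 3.41 against 25.9, 21.9, 22.96 and 23.5 CPM, and Y102A5C.6 was at 8.73, 9.18, 13.4 and 9.03 against 71.2, 63.4, 52.5 and 59.1 CPM. The 6 other tested genes within 50 kb had log2 fold changes from -0.08 to 0.27, and 0 of them passed. Reads that these genes share with similar copies could have been assigned to either by the quantifier, so each single value is uncertain.

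**Figure D2:**
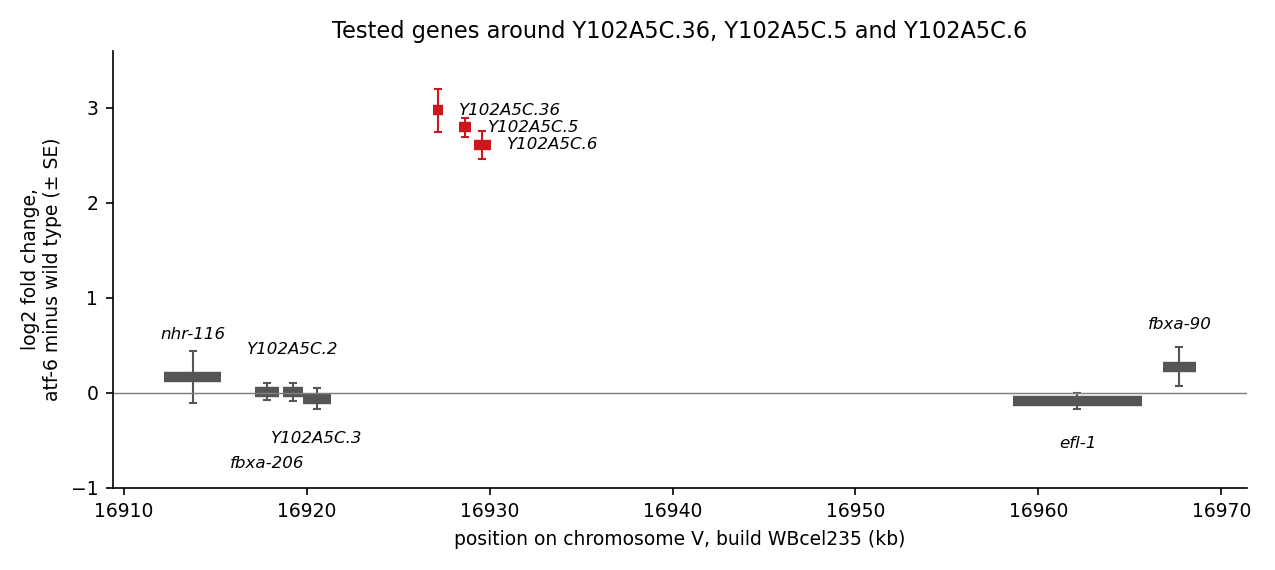
Tested genes around the Y102A5C cluster, placed by their position on chromosome V (horizontal axis, kb, build WBcel235) and their log2 fold change (vertical axis, atf-6 minus wild type, bars show the SE). The 3 genes in red passed an adjusted p of 0.05 and lie between 2.61 and 2.97; the 6 grey neighbours lie between -0.08 and 0.27.

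Among higher genes with a mean log2 CPM of at least 1, the next largest rises were in C55C3.3 (log2 fold change 1.79, SE 0.212) and T10D4.6 (log2 fold change 1.69, SE 0.0891), the latter going from 21.2 ± 2.04 to 68.8 ± 5.59 CPM (SD, n = 4; edgeR adjusted p = 1.00e-05). C48E7.7, Y106G6G.4, R09E10.6 and Y59E9AR.7 rose with log2 fold changes of 1.35, 1.34, 1.32 and 1.30. Under that level, rmd-6, named after its value was seen, rose with a log2 fold change of 1.99 (SE 0.284, edgeR adjusted p = 0.0153). It was not among the genes that passed in every fit with 1 library left out. Among the 13 lower genes, the largest falls at a mean log2 CPM of at least 1 were in F08D12.2 (WBGene00017246, chromosome II, 2781655 to 2783083), Y92H12BL.1 (WBGene00022363, chromosome I, 1348503 to 1359643) and amt-1 (WBGene00000133, chromosome X, 4571437 to 4573914), an ammonium transporter. Their log2 fold changes were -1.84 (SE 0.195), -1.35 (SE 0.0800) and -1.17 (SE 0.157), with edgeR adjusted p of 0.00220, 1.68e-05 and 0.0110. The low-expressed ins-24 had -1.47 (SE 0.238). F08D12.2 had 6.30, 8.38, 9.17 and 7.88 CPM in wild type and 2.72, 2.56, 1.44 and 2.29 CPM in atf-6. Y92H12BL.1 had 39.7, 39.2, 41.8 and 40.9 against 16.3, 16.9, 13.8 and 16.38 CPM, and amt-1 10.5, 10.2, 9.43 and 10.8 against 5.67, 5.42, 3.64 and 3.68 CPM. aco-2, the mitochondrial aconitase of the citric acid cycle, fell from 910.1 ± 97.5 to 592 ± 54.8 CPM (SD, n = 4; log2 fold change -0.62, SE 0.0967, edgeR adjusted p = 0.0242). The filamin gene fln-2 fell from 103 ± 8.52 to 64.4 ± 4.34 CPM (log2 fold change -0.68, SE 0.0762, edgeR adjusted p = 0.00300). The aspartyl protease gene asp-8, C27C7.1, the selenophosphate synthetase gene seld-1, pud-2.2, fip-2, C54D10.3 and F36D3.1 fell with log2 fold changes of -0.80, -0.66, -0.63, -0.62, -0.55, -0.44 and -0.42.

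The number of genes past the threshold varied with the library left out. It was 30, 40, 107 and 16 without wild-type replicates 1, 2, 3 and 4, and 32, 37, 41 and 20 without atf-6 replicates 1, 2, 3 and 4, and 15 genes (11 higher, 4 lower) passed in all of these 8 fits. These 15 included the Y102A5C cluster, C55C3.3, T10D4.6, ckb-2, the sperm-specific family gene sss-1, F08D12.2, Y92H12BL.1, C27C7.1 and fln-2. The others were txdc-12.1, tcl-2, T02G5.4 and Y55F3AM.11, named after their values were seen. Of the 37 genes that passed and that the naming rule took, 11 passed in all 8 fits and 26 lost their call in at least 1. amt-1 (without wild-type replicate 4, adjusted p = 0.0650), asp-8 and his-24 lost it in 1 fit, R09E10.6 in 2, msp-57 in 3 and msp-19 in 4. The other 20 lost it in 5 or more: aco-2 and C48E7.7 in 5, and Y106G6G.4, pud-2.2, fip-2, msp-53, msp-55 and col-159 in 6. Y59E9AR.7, C54D10.3, F36D3.1, acdh-8, hsp-43, msd-2, seld-1, ins-24 and spe-11 lost it in 7, and fbn-1, ssp-16 and ssp-31 in all 8. The highest adjusted p of these genes in any of the fits was 0.199. Y59E9AR.7 also missed the threshold without a filter on low counts (adjusted p = 0.0741), with plain read sums (0.0526) and with 1 surrogate variable, a fit added after the data were seen (0.0606). DESeq2, run on all genes with its own filter, called 194 genes (163 higher, 31 lower), which included all 101, and plain sums of the deposited transcript reads gave 39 (30 higher, 9 lower). A split of the same 8 libraries that crosses the strains, wild-type replicates 1 and 2 with atf-6 replicates 3 and 4 against the rest, gave 544 genes.

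Of the gene lists tested, that of the major sperm proteins held the most of the higher genes. These proteins (MSPs), the cytoskeletal proteins that move nematode sperm, are encoded by a family of nearly identical genes. Of 28 tested family members 13 rose, 0 fell and 15 did not pass over all genes with edgeR, and 28 rose when adjusted over the list alone, with a median log2 fold change of 1.12. Because reads cannot be assigned with certainty among such copies, all 31 family members were also summed. The sum was 100.5, 150.4, 176 and 104.5 CPM in wild-type replicates 1 to 4 and 387, 239, 273 and 271 CPM in atf-6 replicates 1 to 4. The means were 133 ± 36.7 and 292 ± 64.9 CPM (SD, n = 4), 2.20-fold higher in atf-6 (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 allows). Over the 6 families and lists summed, the Benjamini-Hochberg adjusted p was 0.0858. With 4 libraries against 4, an adjusted p under 0.05 needed at least 4 of the 6 sums at that smallest p, and 2 were, so a larger rise of the MSP sum would not have passed either. Among single members, msp-53, msp-55, msp-57 and msp-19 rose with log2 fold changes of 1.61, 1.27, 1.22 and 1.12 (SE 0.275, 0.202, 0.189 and 0.175).

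A separate list of sperm genes moved the same way. Of 17 tested members 4 rose, 0 fell and 13 did not pass over all genes, and 13 rose when adjusted over the list alone, with a median log2 fold change of 1.01. spe-11, which encodes a sperm-supplied factor of the embryo, rose from 0.520 ± 0.169 to 1.68 ± 0.389 CPM (SD, n = 4; log2 fold change 1.62, SE 0.278, edgeR adjusted p = 0.0327). ssp-31, ssp-16 and msd-2, all related to the MSPs, had log2 fold changes of 1.49, 1.18 and 1.15 (SE 0.273, 0.230 and 0.217). Outside this list, sss-1 rose with a log2 fold change of 1.30 (SE 0.161). Summed over the list, sperm transcripts went from 27.02 ± 6.11 to 53.5 ± 5.58 CPM (SD, n = 4; exact permutation test, two-sided p = 0.0286, adjusted p = 0.0858 over the 6 sums). None of the 6 sums passed after adjustment. For the other 4, the exact permutation p was 0.314 for oocyte and germline genes (0.955-fold), 0.971 for vitellogenins (0.995-fold), 0.486 for collagens (1.07-fold) and 0.486 for ribosomal proteins (0.937-fold). By gene class names chosen after the values were seen (msp, msd, ssp, ssq, sss, spe, nspd and msrp), 26 of the 88 higher genes and 0 of the 13 lower genes belonged to sperm classes, and 65 of 71 tested genes of these classes had a positive log2 fold change.

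As sets, the MSP family and the sperm list passed camera with a preset correlation (adjusted p = 2.03e-67 and 9.30e-24). With an estimated correlation neither passed (adjusted p = 0.108 and 0.0592), while the fry test for movement in 1 direction passed for both (adjusted p = 0.0446 and 0.0119). The number of single MSP genes past the threshold also varied with the library left out. It was 1, 2, 18 and 0 without wild-type replicates 1 to 4 and 2, 4, 3 and 0 without atf-6 replicates 1 to 4, with medians between 0.95 and 1.30. For the sperm list it was 0, 1, 3 and 0 without wild-type replicates 1 to 4 and 0 without any 1 of the atf-6 replicates, the lowest median being 0.919. With plain sums of the deposited transcript reads, 1 MSP gene and 1 gene of the sperm list passed. DESeq2 called 26 of 28 MSP genes and 9 of 17 genes of the sperm list, all higher.

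**Figure D3:**
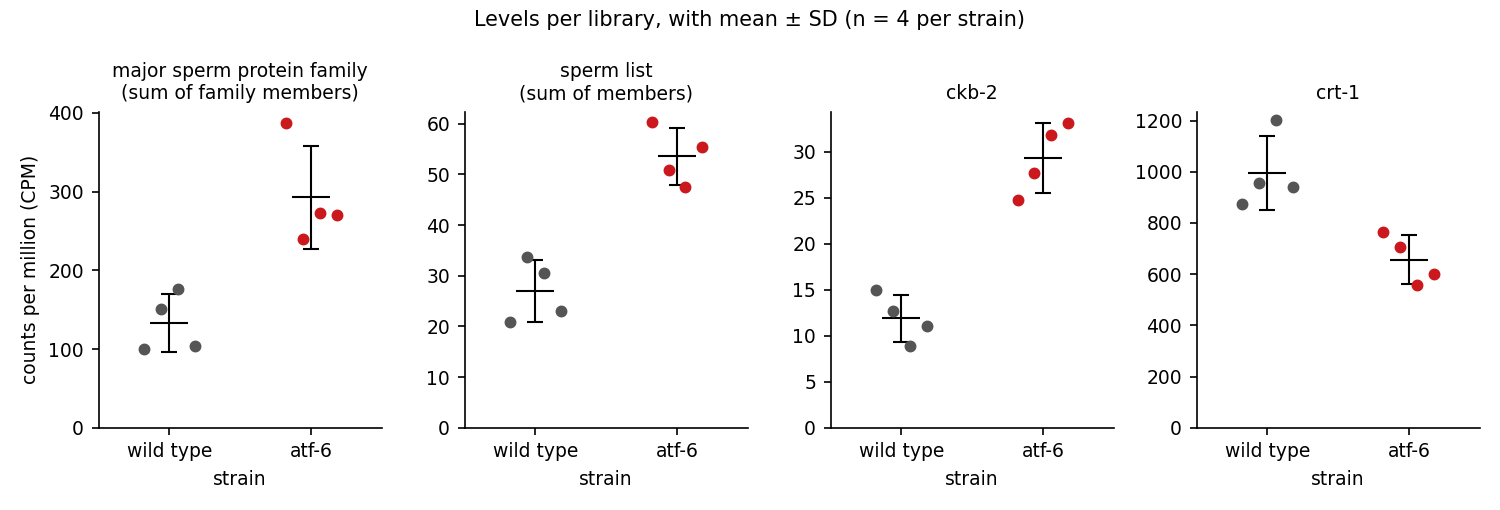
CPM (vertical axes, starting at 0) in each library of wild type (grey) and atf-6 (red) for the summed MSP family, the summed sperm list, ckb-2 and crt-1; horizontal bars are means and whiskers the SD (n = 4). The summed MSP family lies between 100.5 and 176 CPM in wild type and between 239 and 387 CPM in atf-6, and crt-1 between 873 and 1203 CPM in wild type and between 559 and 765 CPM in atf-6.

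Of 100 tested collagen genes, 1 rose (col-159, from 66.9 ± 8.80 to 101 ± 13.9 CPM, SD, n = 4; log2 fold change 0.59, SE 0.114), 0 fell and 99 did not pass over all genes. Adjusted over the list alone, 17 rose and 1 fell, and the family median was 0.28, or 0.14 without wild-type replicate 1. Over all genes, 0 passed with RLE scaling, with plain read sums, and without wild-type replicates 1 or 4 or atf-6 replicates 1, 2 or 4. Without wild-type replicate 2 it was 2, without wild-type replicate 3 it was 5, and DESeq2 called 14 of 105. The family passed camera with a preset correlation (adjusted p = 5.09e-13) but not with an estimated one (adjusted p = 0.708), nor fry (adjusted p = 0.374). Wild-type replicate 1 was the lowest library in this family. Its mean log2 level over the family was -0.88 relative to the mean of the 8 libraries. The other wild-type libraries lay at -0.28 to 0.20 and the atf-6 libraries at -0.07 to 0.51. A shorter list of adult and larval cuticle collagens did not pass (24 tested, 0 past the threshold over all genes with edgeR or adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 of 26 tested with DESeq2, camera adjusted p = 0.114). In the molting list, 1 of 15 tested genes rose over all genes and 1 adjusted over the list alone, fbn-1, a fibrillin-like matrix gene (log2 fold change 0.69, SE 0.127), and the list did not pass camera (adjusted p = 0.0525). It passed fry for movement in 1 direction, upward (adjusted p = 0.0446).

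Innate immune effectors had 0 of 26 tested members past the threshold over all genes with edgeR (7 at an unadjusted p under 0.05, and 1 up and 1 down of 28 tested with DESeq2), and adjusted over the list alone 1 rose (dod-19, log2 fold change 0.40) and 1 fell (the lysozyme gene lys-4, log2 fold change -0.29). The list passed camera with a preset correlation (median 0.17, adjusted p = 0.0245), not with an estimated one (adjusted p = 0.372), and it passed fry (adjusted p = 0.0446). Its camera call was lost without wild-type replicate 1 (adjusted p = 0.0784), wild-type replicate 3 (0.129) or atf-6 replicate 2 (0.136), and without wild-type replicate 3 and atf-6 replicate 3 together, a choice made after seeing the data (0.118).

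The proteasome, ribosome, oocyte and mitochondrial lists that passed camera had medians slightly under 0 with TMM, RLE and upper-quartile scaling, with 0 members past the threshold over all genes with edgeR or DESeq2, or adjusted over the list alone, and at most 1 member of each at an unadjusted p under 0.05. Proteasome subunits (32 tested, all with a negative log2 fold change, median -0.09), cytosolic ribosomal proteins (77 tested, median -0.09) and oocyte and germline genes (34 tested, median -0.07) passed camera with a preset correlation (adjusted p = 1.65e-05, 1.65e-05 and 0.000225). With an estimated correlation none of these passed (adjusted p = 0.654, 0.904 and 0.654). The ribosomal call was lost without wild-type replicate 3 (adjusted p = 0.682) or atf-6 replicate 3 (0.176). Without both of these libraries, a choice made after seeing the data, it turned upward (0.0290) and the proteasome, oocyte and mitochondrial ribosomal calls were lost (0.118, 0.173 and 0.173). Mitochondrial ribosomal proteins (69 tested, median -0.04) and electron transport chain and ATP synthase subunits (34 tested, median -0.06) passed with the preset correlation (adjusted p = 0.0314 and 0.0423) and not with the estimated one (adjusted p = 0.511 and 0.904). The mitochondrial ribosomal call was lost without wild-type replicate 4 (adjusted p = 0.0555), atf-6 replicate 1 (0.0746) or atf-6 replicate 3 (0.178). The electron transport call was lost without wild-type replicate 3 (0.966), atf-6 replicate 3 (0.692) or atf-6 replicate 4 (0.144), without the genes within 2 Mb of atf-6 (0.0527) and with 1 surrogate variable, added after the data were seen (0.4504). None of these 5 lists passed fry for movement in 1 direction, where the smallest adjusted p was 0.253. Mitochondrial chaperones and genes of the mitochondrial UPR had 0 of 17 tested members past the threshold with edgeR or DESeq2 (0 at an unadjusted p under 0.05) and did not pass camera (median -0.09, adjusted p = 0.0752).

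Single genes of other lists passed over all genes: hsp-43, a small heat shock protein gene (log2 fold change 0.32, SE 0.0548), the linker histone gene his-24 (0.70, SE 0.0926), the acyl-CoA dehydrogenase gene acdh-8 (1.28, SE 0.237) and the insulin-like peptide gene ins-24 (-1.47, SE 0.238). Their lists did not pass camera: the cytosolic heat shock response (16 tested, adjusted p = 0.883), histones (40 tested, 0.178), lipolysis and fatty acid oxidation (25 tested, 0.499) and neuropeptides (95 tested, 0.878). ER-associated degradation (15 tested, camera adjusted p = 0.185), ER translocation and N-glycosylation (16 tested, 0.499) and vitellogenins, the yolk proteins (6 tested, 0.866), did not pass either. ER-associated degradation did pass fry for movement in 1 direction, downward (median -0.05, adjusted p = 0.0446). Tissue markers of intestine, body-wall muscle, neurons and pharynx did not pass camera (adjusted p = 0.742, 0.547, 0.883 and 0.499). In all, 9 of the 42 lists passed camera with the preset correlation and 0 with an estimated one, where the smallest adjusted p was that of the sperm list.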

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

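Dixon's test for 1 library far from the other 3 of its group was run on the named genes and the list levels, in 176 groups, where chance alone gives about 8.8. It singled out 4. hsp-4 in wild-type replicate 3 was at 533 CPM, with the others between 459 and 470.2 CPM. Y102A5C.6 in wild-type replicate 3 was at 13.4 CPM, with the others between 8.73 and 9.18 CPM. sss-1 in atf-6 replicate 2 was at 4.84 CPM, with the others between 6.33 and 6.60 CPM, and msp-19 in atf-6 replicate 1 was at 21.3 CPM, with the others between 12.998 and 14.4 CPM. No technical explanation was weighed for these 4 values, and no gene list had such a library.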

How the results depend on the processing

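Tests with 1 surrogate variable, with a transcript length offset and without the 2 libraries at the ends of that variable were chosen after seeing the data; the others were planned. The 101 genes (88 higher, 13 lower) became 96 to 106 with RLE, upper-quartile scaling, limma-voom, 10 counts in 4 libraries or the length offset, and 136 without a filter (20 lower). Without those 2 libraries, 68 of the 101 genes were also called. DESeq2 gave 194 (163 higher, 31 lower; 101 shared), plain read sums 39 (30 higher; 38 shared), a threshold of 0.01 15 (11 higher, 4 lower), and 1 surrogate variable 328 (266 higher, 62 lower; 99 shared). Leaving out 1 library gave 16 to 107 genes (12 to 92 higher, 4 to 15 lower); these fits have fewer samples, and for the other settings the cause was not tested. The log2 fold change of atf-6 stayed between 0.22 and 0.32 in all settings and passed only with 1 surrogate variable (0.30, adjusted p = 0.0473; adjusted p 0.291 to 0.999 in the others). The 9 lists became 0 with an estimated correlation and 5 with fry, 6 to 11 without 1 library, and 8 to 11 in the other settings. Without those 2 libraries, the electron transport (adjusted p = 0.0817) and ribosomal protein lists (adjusted p = 0.0290) turned to higher in atf-6. Of 46 named genes, 5 changed sign in some setting (hsp-3, hsp-4, ire-1, mcu-1 and pek-1), none of which passed as reported. Same-numbered libraries of the strains did not deviate together (correlations -0.385, -0.0446, -0.407 and 0.043), so no pairing by number was seen. Wild-type replicate 3 and atf-6 replicate 1 correlated at 0.458, and a weaker pairing by number could be hidden under such differences. With the replicate block 4 genes passed (3 higher, 1 lower), all among the 101, and 8 lists, the electron transport list being lost (camera adjusted p = 0.0568). The adjusted p of crt-1 ran from 1.64e-08 with 1 surrogate variable to 0.486 with the replicate block. At this depth, spread and number of libraries together, the simulation, which drew each gene independently, recovered 50% of genes changed 1.5-fold. Depth alone was not varied.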

Other observations

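The tests on basement membrane genes, on transcripts, on the flanks of the Y102A5C cluster and on transcript length were chosen after the gene-level results were seen. lam-2 and epi-1, which encode the gamma chain and an alpha chain of laminin, the main glycoprotein of basement membranes, rose from 58.8 ± 1.73 to 75.7 ± 3.02 CPM and from 122 ± 7.33 to 152 ± 7.33 CPM (SD, n = 4; log2 fold changes 0.36 and 0.32, SE 0.0572 and 0.0628, edgeR adjusted p = 0.0253 and 0.0484). A hypothesis from these is that basement membrane genes may be higher as a set in atf-6. Over 22 other basement membrane genes (structural proteins, receptors and remodelling enzymes), 21 had a positive log2 fold change, with a median of 0.14, and 0 passed singly with edgeR, where 5 had an unadjusted p under 0.05. The other laminin chains lam-1 and lam-3 had log2 fold changes of 0.31 and 0.35, and the perlecan gene unc-52 of 0.42. The 22 genes as a set had camera p-values of 2.59e-05 with a preset and 0.00461 with an estimated correlation. Both are unadjusted, whereas the fixed lists were judged after adjustment over the lists. With an estimated correlation the MSP family and the sperm list had unadjusted camera p-values of 0.00512 and 0.00141. After adjustment neither passed (adjusted p = 0.108 and 0.0592), so the unadjusted 0.00461 is not a stronger result than theirs. The mean level of the 22 genes, on the log2 scale relative to the 8 libraries, was 0.0160 to 0.129 in the atf-6 libraries. In the wild-type libraries it was lower, at -0.107 to -0.0521. The set was chosen because 2 of its genes had passed, so this remains a hypothesis.

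Of 17800 transcripts tested with edgeR in the same way, 10 passed (6 higher, 4 lower), and 3 of these belong to genes whose total did not. The transcript ZK54.2a.3 of tps-1, a trehalose-6-phosphate synthase gene, went from 0.0332 ± 0.0121 to 2.11 ± 0.277 TPM (SD, n = 4; edgeR adjusted p = 0.00197), while the gene total had a log2 fold change of 0.15 (SE 0.0900). The transcript F57F5.4a.2 of add-2, an adducin gene, was estimated at 2.33 ± 0.648 TPM in wild type and at 7.50e-07 ± 1.50e-06 TPM in atf-6 (edgeR adjusted p = 0.0244; gene total 0.20, SE 0.132), and F28C6.4b.2 of pigg-1 at 0.523 ± 0.0800 and 0.000434 ± 0.000863 TPM (edgeR adjusted p = 0.0454; gene total 0.08, SE 0.151). Of 14 tested transcripts of fln-2, which was lower as a gene, 0 passed with edgeR. The smallest adjusted p among them was 0.157, for C23F12.1i (1.25 ± 0.301 TPM in wild type and 0.184 ± 0.103 TPM in atf-6). Isoforms of a gene overlap, so these values depend on how the quantifier divided shared reads.

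Other splits of the 8 libraries did not exclude chance for the 101 genes. Of the 35 splits into 4 and 4, 2 gave at least as many genes, a share of 0.0571: the real one and the split of wild-type replicates 1 and 2 with atf-6 replicates 3 and 4 against the rest, which gave 544, while the other 33 gave at most 1. That split crosses the strains and points to a structure of the samples other than the strain. The surrogate variable divided the libraries in the same way by its sign, with wild-type replicate 4 near 0 (0.00908). A transcript length trend left in the count table was weighed for it: an offset for length took the largest correlation of a library's deviations with length from -0.104 to -0.0278 (Spearman, across genes), and the split then gave 577 genes, which argues against that trend as the whole cause; GC content, RNA quality and culture differences stay open and were not tested. Variants linked to atf-6 stay open, as do variants at other places: 0% of 403 tested genes within 2 Mb of atf-6 passed, against 0.844% of 11972 elsewhere (two-sided Fisher's exact test, p = 0.0814), but that difference did not pass and a linked variant can change genes anywhere, so where the 101 genes lie does not decide it.

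The higher level of sperm transcripts in atf-6 was weighed against 2 explanations. With the transcript length offset the median log2 fold change of the MSP family was 1.1, against 1.12 without it, which argues against a length trend left in the count table, whose fitted size for these genes lay between -0.108 and 0.152 (log2) over the libraries. A candidate explanation is a difference in developmental timing, since hermaphrodites make sperm before oocytes and all worms were collected at 1 time. Of 7 stage lists (oocyte and germline, sperm, early embryo, vitellogenins, molting, cuticle collagens and the collagen family), 3 passed camera with a preset correlation and 0 with an estimated one. Sperm and the collagen family moved upward, and oocyte and germline downward. The sperm list is the pattern to be explained, so it cannot count for timing. The collagen and the oocyte lists did not pass fry for movement in 1 direction (adjusted p = 0.374 and 0.354). Nor did early embryo, vitellogenins and cuticle collagens (fry adjusted p = 0.424, 0.953 and 0.705). The molting list did pass fry, upward (adjusted p = 0.0446), but not camera with a preset correlation (adjusted p = 0.0525). Of the 6 lists other than sperm 1, molting, had groups that did not overlap. With 1 time point per strain, timing and a direct effect of the strain cannot be told apart, and other causes were not tested.

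For the Y102A5C cluster, a gained block of chromosome that reaches the flanking genes was weighed. The 6 other tested genes within 50 kb had a median log2 fold change of 0.0109, and the highest was 0.27, far under the rise of 2.61 to 2.97 in the cluster, which argues against such a block. A change of the 3 genes alone, in copy number or in transcription, and reads shared with similar copies elsewhere stay open, as does an effect of the strain, and none of these was tested.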
